A study of Homo sapiens with 10 samples.

How the data were processed

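ChIP-seq was made in MCF-7 cells with antibodies to ERα, ERβ, SRC3 and RIP140. All cells received 20 nM siRNA for 48 h and 10 nM estradiol for 45 min. ERα-only cells had an empty adenovirus and control siRNA, ERα/ERβ cells an adenovirus for ERβ at a level equal to that of ERα and control siRNA, and ERβ-only cells the ERβ adenovirus and siRNA against ERα. ERα was profiled in ERα-only and ERα/ERβ cells, ERβ in ERα/ERβ and ERβ-only cells, and SRC3 and RIP140 in all 3.

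The authors deposited 1 list of called sites for each of the 10 combinations. Per the submitters' processing notes, sites were called with MACS on genome build hg18. The MACS version, threshold, aligner, control library, number of reads and any pooling of replicates are not given in the sources used here. Each deposited file has 3 columns, chromosome, start and end, and its values are positions in bp (a unit other than counts or intensities), with no height, fold, score or p-value. Starts were checked to count from 0, no site lay beyond the end of its hg18 chromosome, and 0 to 2 sites per list were not fully inside hg18 sequence contigs, which take up 92.8% of the chromosome length. No list held overlapping sites. Because depth and height are unknown, neither could be used for scaling, matching or ranking, and site width took the place of a score.

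A site counted as shared when it overlapped a site of the other list by at least 1 bp. For each share between 2 lists, a 95% Wilson interval was computed. Its ratio to the mean share over 1000 circular shifts of the other list within each chromosome (random seed 20240611) was computed too. The text prints part of these, and shares of classes of sites have intervals but no ratio to shifts. Differences between shares of 2 classes of sites have 95% Newcombe intervals. With 1 list per group, no test across replicates could be made, and no p-values were computed, since sites are not replicates. Receptor sites of ERα/ERβ cells are the merged union of the ERα and ERβ lists (25983 regions). The merged union of the 4 receptor lists was split by the lists each region was called in. Coregulator shares at receptor sites used the coregulator lists of the same cells, except for the merged regions of the 4 receptor lists, where the coregulator lists of all cells were used. Lists of the same antibody were compared in length only as ratios. A simulation on 37898 random sites with 0%, 25.0%, 50% and 75.0% planted overlaps gave back 1.09%, 25.8%, 50.5% and 75.3%.

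Sites were counted per chromosome and per hg18 cytogenetic band (862 bands). Bands known to be amplified in MCF-7 (51 bands, 6.15% of band length, in 1p13, 1q21 to 1q44, 3p14, 17q22 to 17q25 and 20q12 to 20q13) were marked from general knowledge of the cell line. The sites and bands named are the 3 widest sites per list and class, the 5 bands with the most sites per Mb among bands with at least 20 sites, and the 3 bands with the highest and the 3 with the lowest shared share among bands with at least 50 sites; the text prints part of these. Sites on chromosome Y are not discussed, although some (3631 to 7322 bp) were among the 3 widest ERα or ERβ sites not shared with the compared list. Genes given with a band are background and were not assigned to sites.

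The comparisons, tests, naming rules and alternatives were fixed before the data were examined. The alternatives were an overlap of at least 50% of the shorter site, sites within 500 bp, the widest 50% of each list, the longer list reduced to the length of the shorter by width, removal of the amplified bands, merging of touching sites, and random draws from the union of all 10 lists as the chance reference. No draws were sampled. Their expected value was used, which is the share of the merged regions of that union that overlap the list. The tests in the closing section were chosen later. For 1 of them, tRNA and protein-coding genes were counted per chromosome in the GRCh38.p14 annotation, without using positions.

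Distances to genes, the planned counts of estrogen-regulated and other gene lists near sites with their 20 kb and 100 kb windows, and motif counts were left out, because they need a gene annotation and a genome sequence on hg18, which were not used here. The planned substitute, hg18 microRNA target sites of the rtracklayer package, is keyed by Ensembl transcripts, which the reference table used here does not pair with gene symbols, so it was left out too. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Bands and chromosome lengths came from R 4.3.3 with circlize 0.4.16, GenomeInfoDb 1.38.1 and IRanges 2.36.0.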

Results

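Sites bound by ERα, ERβ and the coregulators SRC3 (NCOA3, a p160 coactivator) and RIP140 (NRIP1, a ligand-dependent corepressor) were compared in MCF-7 breast cancer cells treated with 10 nM estradiol for 45 min. ERα-only cells carried endogenous ERα. ERα/ERβ cells also expressed ERβ from an adenovirus, and ERβ-only cells expressed ERβ after ERα was depleted by siRNA. The 10 lists held 37898 ERα sites in ERα-only cells and 19950 in ERα/ERβ cells, 20228 ERβ sites in ERα/ERβ cells and 37757 in ERβ-only cells. SRC3 had 4030, 6831 and 6053 sites, and RIP140 2118, 2511 and 8924, in ERα-only, ERα/ERβ and ERβ-only cells. Median widths were 535 to 759 bp for the receptor lists and 332 to 357 bp for the coregulator lists, except for RIP140 in ERβ-only cells (650 bp). There were no replicates, so every value describes 1 list per antibody and kind of cell. Intervals are 95% Wilson intervals and cover counting error only. Antibodies and library depths may differ between lists, so the lengths of lists made with different antibodies were not compared as binding.

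With ERβ present, far fewer ERα sites were called, and most ERα sites of ERα-only cells were not called again. The sites that were called with ERβ present were mostly sites that ERα already occupied without it, with a smaller set seen only when ERβ was there. The sites that dropped out were largely places where ERβ was not called either. The ERα list fell by 47.4%. Of the 37898 ERα sites in ERα-only cells, 14562 (38.4%, 37.9–38.9) overlapped an ERα site in ERα/ERβ cells, 42.4 times the mean of 0.907% over 1000 circular shifts and 1.19 times random draws from the union of all 10 lists, and 23336 did not. The union contains the compared lists themselves, which holds ratios to the draws low, the more so the longer the lists. In the other direction, 74.6% (74.0–75.2; 42.8 times the shifts and 1.19 times the draws) of ERα sites in ERα/ERβ cells were also called in ERα-only cells, and 5072 were not. Of the 5072, 61.5% (60.1–62.8) carried ERβ in the same cells, against 74.0% (73.2–74.7) of the others. ERβ of ERα/ERβ cells lay at 8.19% (7.84–8.55) of the ERα sites that dropped out and at 74.1% (73.4–74.8) of those that were kept. In ERβ-only cells, ERβ lay at 22.6% (22.03–23.10) and 87.7% (87.2–88.2) of these classes. Kept sites had a median width of 740 bp in ERα-only cells and the others 629 bp. In ERα/ERβ cells, the ERα sites that overlapped an ERα site of ERα-only cells were narrower (median 561 bp), so the 2 ERα lists are not alike in width. With the longer list reduced to its 19950 widest sites, the shares in the 2 directions were 46.4% and 48.2% instead of 38.4% and 74.6%. Both directions count nearly the same overlaps, so lists of equal length give nearly equal shares by construction. The narrower gap is therefore no separate result, and the reduction also keeps only the widest sites.

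ERβ was called at more sites when ERα was depleted. Nearly all ERβ sites of ERα/ERβ cells were still called in ERβ-only cells, and about as many further ERβ sites were called in addition. Most of the further sites were places without ERα in either of the other kinds of cells. The ERβ list of ERβ-only cells was 1.87 times as long as that of ERα/ERβ cells. It contained 92.9% (92.6–93.3) of the ERβ sites of ERα/ERβ cells, 39.5 times the mean of the shifts and 1.48 times the draws from the union. In the other direction, 49.5% (48.95–49.96) of ERβ sites in ERβ-only cells were called in ERα/ERβ cells, 38.8 times the mean of the shifts and 1.49 times the draws, and 19084 were not. ERα of ERα/ERβ cells lay at 3245 of these 19084 sites (interval 16.5–17.5%) and at 72.3% (71.6–72.9) of the shared ones. For ERα of ERα-only cells the shares were 29.3% (28.6–29.9) and 65.8% (65.1–66.5). The ERβ-only sites differ from ERα/ERβ sites by the siRNA as well as by ERα, and a library with more reads would also lengthen the list.

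When present together, ERα and ERβ were called largely at the same places. When each was the only receptor, fewer than 50% of the sites of either were also sites of the other. In ERα/ERβ cells, 70.8% (70.1–71.4) of ERα sites overlapped an ERβ site (66.5 times the mean of the shifts), and 68.4% (67.8–69.1) of ERβ sites overlapped an ERα site (66.6 times). With each receptor alone, the shares were 47.6% (47.1–48.1; 22.9 times) for ERα sites and 47.3% (46.8–47.8; 22.7 times) for ERβ sites. These lists are of similar length, and reducing the longer to the length of the shorter left 47.7% and 47.2%. Measured against random draws from the union of all 10 lists rather than against shifted positions, the overlap of the receptors alone was 0.760 and 0.755 times the draws, and that of the receptors together 2.13 and 2.12 times. The lists of the receptors alone make up most of that union, so a ratio below 1 is nearly fixed by their length and does not show that the receptors avoided each other.

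**Figure D1:**
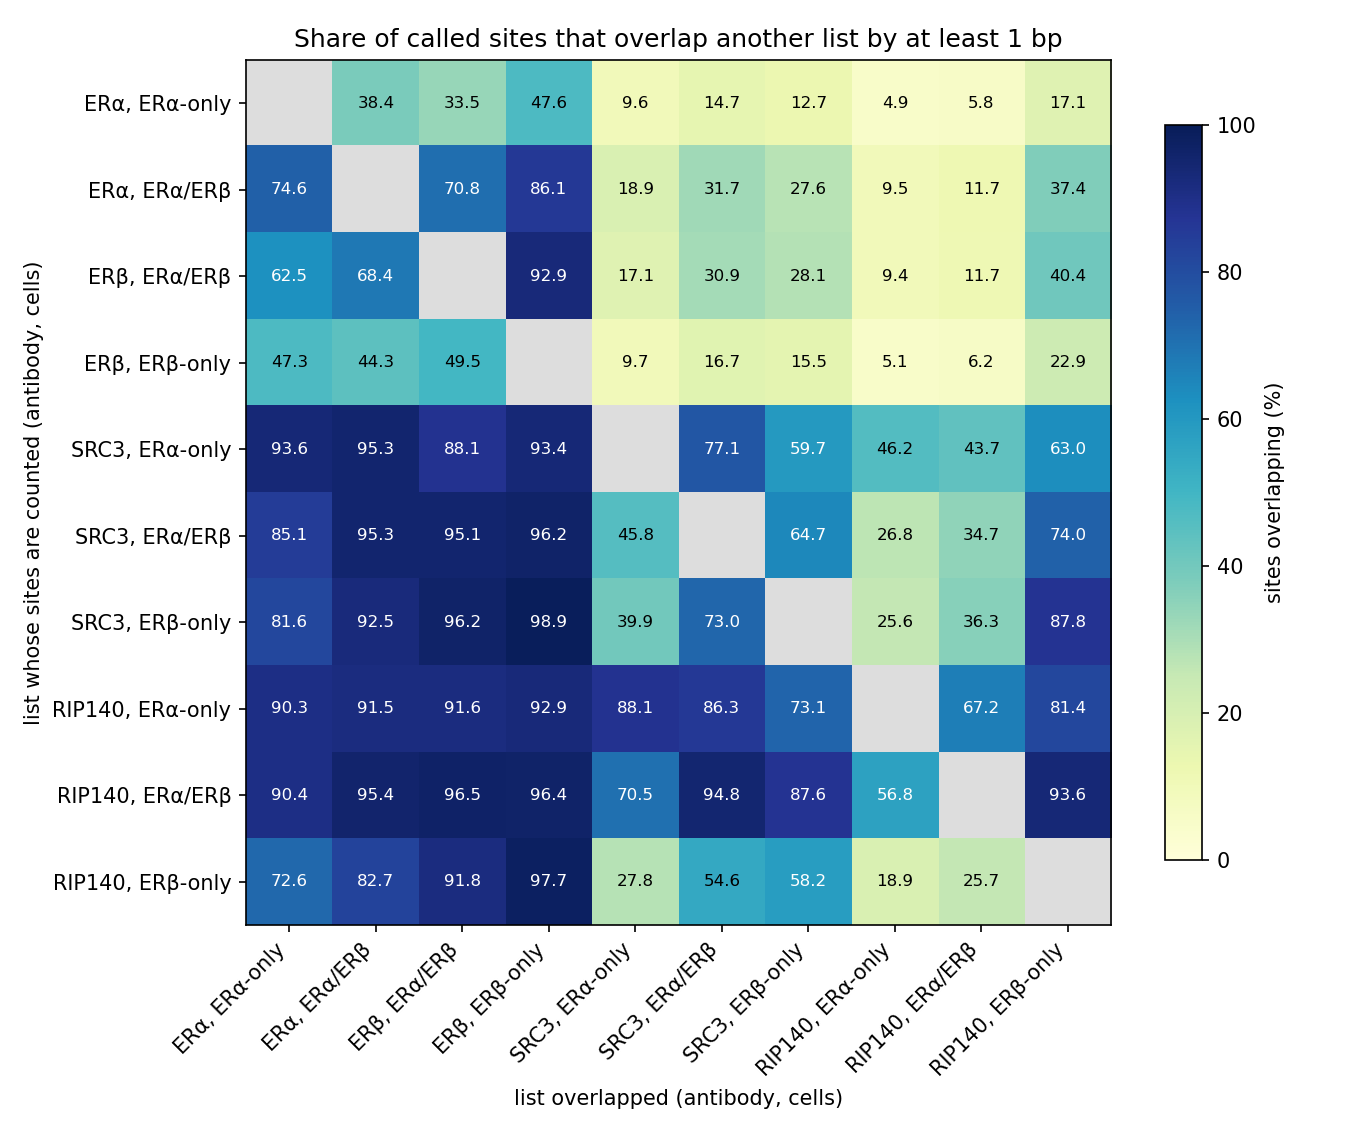
Percent of the sites of each list (vertical axis) that overlap a site of each other list (horizontal axis) by at least 1 bp, for the 10 lists. ERα and ERβ of ERα/ERβ cells share 70.8% and 68.4% of their sites, the receptors alone 47.6% and 47.3%, and nearly all coregulator sites lie at receptor sites of the same cells.

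Across the 4 receptor lists, a large part of the binding landscape was private to 1 list, and a smaller core was called in all 4 lists, that is, for each receptor with and without the other. Coregulators were concentrated in that core. The merged receptor sites formed 59141 regions. Of these, 32184 (54.4%) were called in 1 list, with 17901 for ERα in ERα-only cells and 12407 for ERβ in ERβ-only cells as the largest classes, and 10450 (17.7%) were called in all 4. Any of the 6 coregulator lists had a site at 71.9% (71.0–72.8) of the 10450 core regions. For the regions with ERα in ERα-only cells alone the share was 0.184% (0.131–0.259), and for those with ERβ in ERβ-only cells alone 2.76% (2.49–3.07). Private regions have no called receptor in the cells of some of these lists, which widens the contrast. By the lists of ERα-only cells, SRC3 lay at 31.4% of core and 0.145% of the ERα regions, and RIP140 at 17.3% and 0.0112%. By those of ERβ-only cells, SRC3 lay at 44.2% of core and 0.532% of the ERβ regions, and RIP140 at 56.2% and 2.37%. Of the 11148 regions with any coregulator, 67.4% were core regions, and 1166 regions were called in all 10 lists. Regions bound by both receptors in ERα/ERβ cells and by ERβ in ERβ-only cells, but not by ERα in ERα-only cells, numbered 2871. SRC3 lay at 3.03% (2.46–3.72) of these in ERα-only cells, 23.3% (21.8–24.8) in ERα/ERβ cells and 26.2% (24.6–27.8) in ERβ-only cells. RIP140 lay at 0.940% (0.647–1.36), 4.04% (3.38–4.82) and 43.4% (41.6–45.2). The low shares in ERα-only cells are largely set by the choice of regions without ERα there. In those cells 93.6% of SRC3 sites and 90.3% of RIP140 sites lay at ERα sites. Core regions were also wide (median 1012 bp, against 624 and 682 bp for the private classes), in part because merged sites of 4 lists span more sequence.

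**Figure D2:**
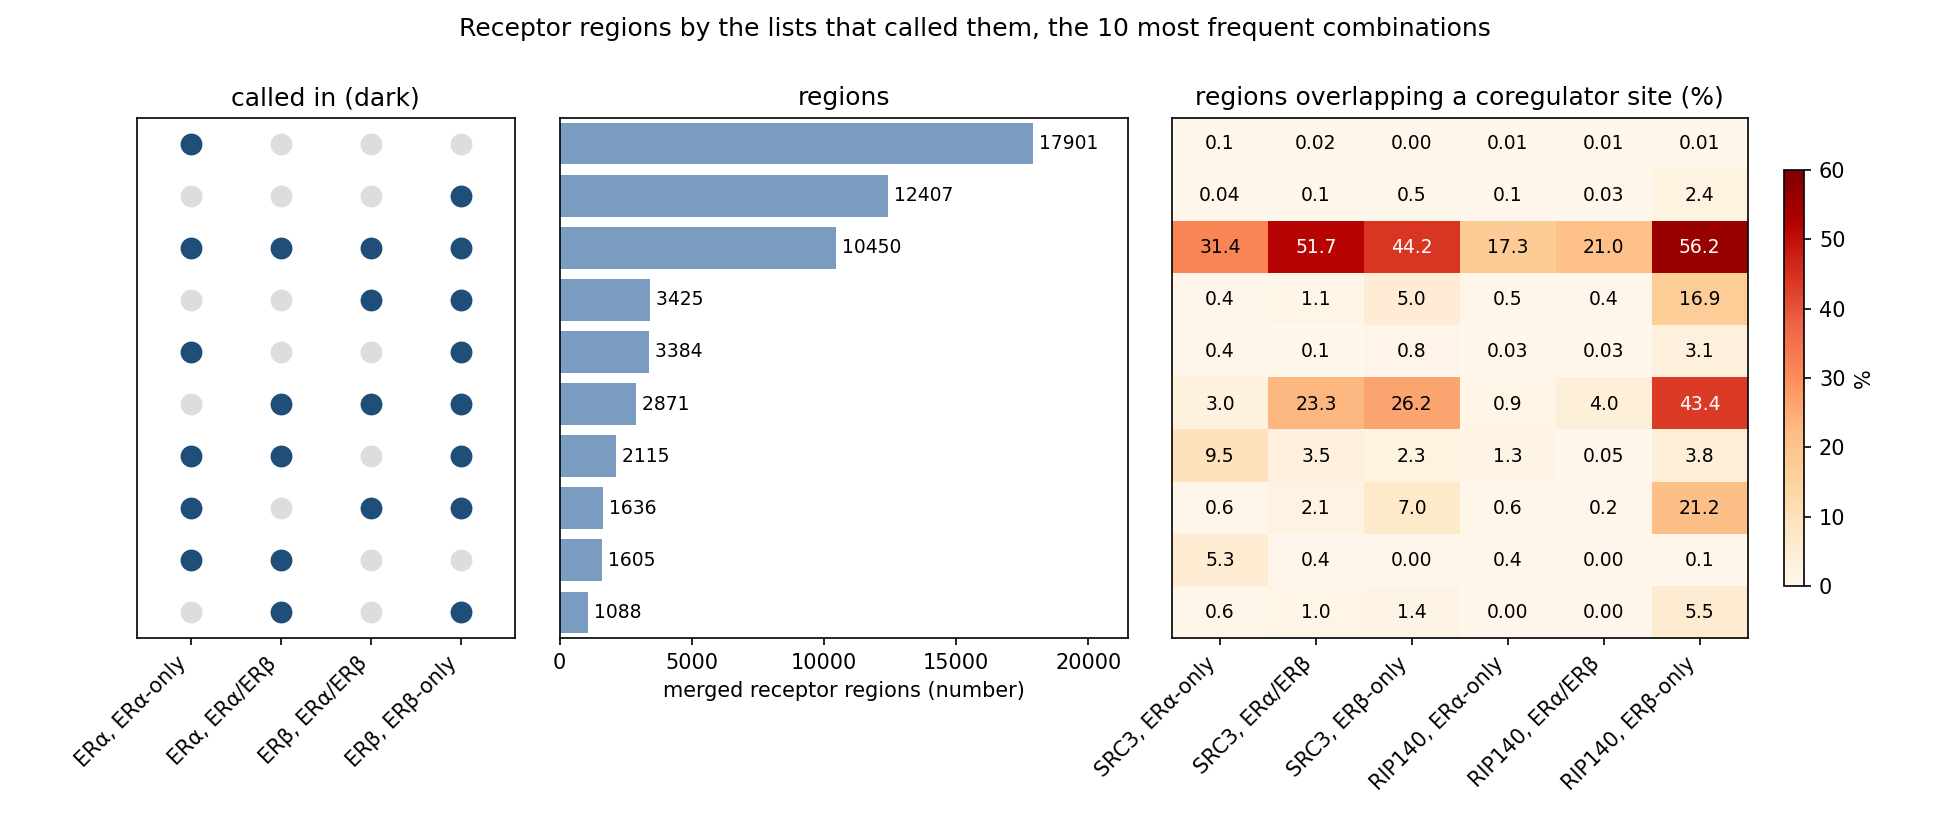
Number of merged receptor regions (bars) for the most frequent combinations of receptor lists they were called in, and percent of the regions with a site of each of the 6 coregulator lists. The share with a site of any coregulator list is not drawn. It was 71.9% for the 10450 regions of all 4 lists, against 0.184% for the 17901 regions of ERα in ERα-only cells alone. The latter have no called receptor in the cells of some of the 6 lists, which widens the contrast.

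SRC3 was found almost only at receptor sites, whichever receptor the cells had. More SRC3 sites were called in ERα/ERβ cells than in ERα-only cells, and most sites of ERα-only cells were among them. Most SRC3 sites of ERα/ERβ cells were also called in ERβ-only cells. Read depth is not known, so the lengths of the SRC3 lists need not reflect recruitment. The SRC3 list of ERα/ERβ cells was 1.70 times as long as that of ERα-only cells, and the list of ERβ-only cells 0.886 times as long as that of ERα/ERβ cells. Of SRC3 sites in ERα-only cells, 77.1% were called in ERα/ERβ cells (414 times the mean of the shifts and 7.10 times the draws from the union), as were 73.0% of those in ERβ-only cells (401 and 6.71 times). Of SRC3 sites in ERα/ERβ cells, 45.8% were called in ERα-only cells and 64.7% in ERβ-only cells. In the merged 9259 SRC3 regions, 2310 were called in all 3 kinds of cells, 2080 in the 2 with ERβ, 787 in the 2 with ERα, and 87 in ERα-only and ERβ-only cells but not in ERα/ERβ cells. Receptor sites of the same cells lay at 93.6% of SRC3 sites in ERα-only cells, 96.6% in ERα/ERβ cells and 98.9% in ERβ-only cells, 62.2, 86.9 and 58.2 times the means of the shifts but 1.49, 2.26 and 1.58 times draws from the union of all lists. When receptor lists were reduced to as many of their widest sites as there were SRC3 sites, these shares were 36.0%, 45.4% and 32.1%. Most SRC3 sites thus lay at receptor sites outside the widest ones, although wide sites carried SRC3 more often. Among ERα sites of ERα-only cells kept in ERα/ERβ cells, SRC3 lay at 8.36% of the narrowest of 4 width classes and at 41.9% of the widest.

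RIP140 was called at few sites while ERα was present and at several times as many in ERβ-only cells. Almost all RIP140 sites of ERα/ERβ cells, and most of those of ERα-only cells, were found again in ERβ-only cells, and the much longer list added sites that were already receptor sites. RIP140 was also found almost only at receptor sites. The RIP140 list of ERα/ERβ cells was 1.19 times as long as that of ERα-only cells, and the list of ERβ-only cells 3.55 times as long as that of ERα/ERβ cells. The ERβ-only list contained 93.6% of RIP140 sites of ERα/ERβ cells and 81.4% of those of ERα-only cells. In the other direction, 25.7% of RIP140 sites in ERβ-only cells were called in ERα/ERβ cells (234 times the mean of the shifts and 6.32 times the draws from the union). With the ERβ-only list reduced to its 2511 widest sites, that share was 39.8%, and the share of RIP140 sites of ERα/ERβ cells found in ERβ-only cells was 42.1% instead of 93.6%. Of RIP140 sites in ERα-only cells, 67.2% were called in ERα/ERβ cells (871 and 16.5 times), and of those in ERα/ERβ cells, 56.8% were called in ERα-only cells (810 and 16.6 times). Receptor sites of the same cells lay at 90.3%, 96.6% and 97.7% of RIP140 sites in ERα-only, ERα/ERβ and ERβ-only cells (57.9, 83.4 and 44.4 times the shifts; 1.44, 2.26 and 1.56 times the draws), and at 29.8%, 28.0% and 42.2% with the receptor lists reduced to the same number of widest sites. Of the merged 9402 RIP140 regions, 6274 (66.7%) were called in ERβ-only cells alone and 1328 in all 3 kinds of cells. The sites of the ERβ-only list were wider than those of the other RIP140 lists even where they coincided, so the RIP140 lists are not alike in resolution, and their lengths are compared with that limit.

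RIP140 was called almost only at sites that SRC3 also occupied while ERα was present, and at many sites without SRC3 in ERβ-only cells. Of RIP140 sites, 88.1% in ERα-only cells, 94.8% in ERα/ERβ cells and 58.2% in ERβ-only cells overlapped an SRC3 site of the same cells (766, 488 and 237 times the means of the shifts; 13.6, 8.72 and 5.91 times the draws from the union). Of SRC3 sites, 46.2%, 34.7% and 87.8% overlapped a RIP140 site. With lists of equal length the order changed: 70.1%, 68.1% and 63.5% of RIP140 sites and 69.7%, 67.6% and 65.5% of SRC3 sites overlapped the other coregulator, and this reduction also keeps the widest sites, so list length and width were not separated. At the receptor sites themselves, SRC3 and RIP140 together were called at 4.72% (4.51–4.94) of sites in ERα-only cells, 8.86% (8.52–9.21) of the 25983 receptor regions in ERα/ERβ cells and 13.7% (13.33–14.02) in ERβ-only cells. SRC3 without RIP140 lay at 4.90%, 15.5% and 1.78%, and RIP140 without SRC3 at 0.190%, 0.185% and 9.25%. Either coregulator lay at 9.81% (9.52–10.1), 24.5% (23.97–25.02) and 24.7% (24.3–25.1).

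Receptor sites that were shared between the compared lists carried SRC3 and RIP140 more often than private sites in every split made. Each coregulator was still called at fewer than 50% of the sites of any class in these splits, and its share of private sites ranged from 0.0172% to 14.2%. ERα sites that were called only without ERβ were nearly free of SRC3 and RIP140, and ERα sites without ERβ in ERα/ERβ cells were too. ERα sites gained in the presence of ERβ carried SRC3 of ERα/ERβ cells more often than lost sites carried SRC3 of ERα-only cells. These SRC3 lists differ in length. Of ERα sites in ERα-only cells, SRC3 lay at 24.7% (24.03–25.44) of those kept in ERα/ERβ cells and at 0.193% (0.144–0.258) of those not called there, a difference of 24.5 points (23.8–25.2); for RIP140 the shares were 12.7% (12.2–13.3) and 0.0300% (0.0145–0.0619). Of ERα sites in ERα/ERβ cells, SRC3 lay at 44.02% (43.21–44.84) with ERβ and at 1.72% (1.41–2.08) without it (42.3 points, 41.4–43.2), and RIP140 lay at 16.6% (16.0–17.2) and at 1 of 5830. ERβ sites in ERα/ERβ cells gave the mirror image, with SRC3 at 44.6% with ERα and 1.253% without it, and RIP140 at 16.8% and 0.407%. ERα sites gained with ERβ had SRC3 at 14.2% (13.3–15.2) and RIP140 at 2.41% (2.02–2.86), against 37.6% and 14.9% of the ERα sites already present.

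For ERβ sites the direction was the same, but the sizes of the contrasts differed. In ERβ-only cells, SRC3 lay at 30.4% (29.7–31.1) of ERβ sites also called in ERα/ERβ cells and at 0.833% (0.714–0.972) of the others. RIP140 lay at 43.4% (42.7–44.2) and 2.85% (2.62–3.10), a difference of 40.6 points (39.8–41.3). ERβ sites of ERα/ERβ cells that were kept in ERβ-only cells carried SRC3 at 33.1% and RIP140 at 12.5%, against 2.03% and 0.701% of the 1427 that were not kept; the SRC3 difference of 31.0 points was 17.7 in the widest 50% of each list and 16.1 with lists of equal length. With each receptor alone, SRC3 lay at 19.5% of ERα sites that were also ERβ sites and at 0.639% of the others, and at 27.0% and 5.07% of ERβ sites by the same split. RIP140 lay at 36.1% of ERβ sites of ERβ-only cells that were ERα sites of ERα-only cells and at 11.1% of the rest. For ERα sites of ERα-only cells, split by ERβ sites of ERβ-only cells, RIP140 lay at 10.3% and 0.0503%. The RIP140 lists of these cells are of unlike length. Shared sites were wider in 6 of the 8 splits by cells and receptor, and the files hold no height by which sites of equal signal could be matched.

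**Figure D3:**
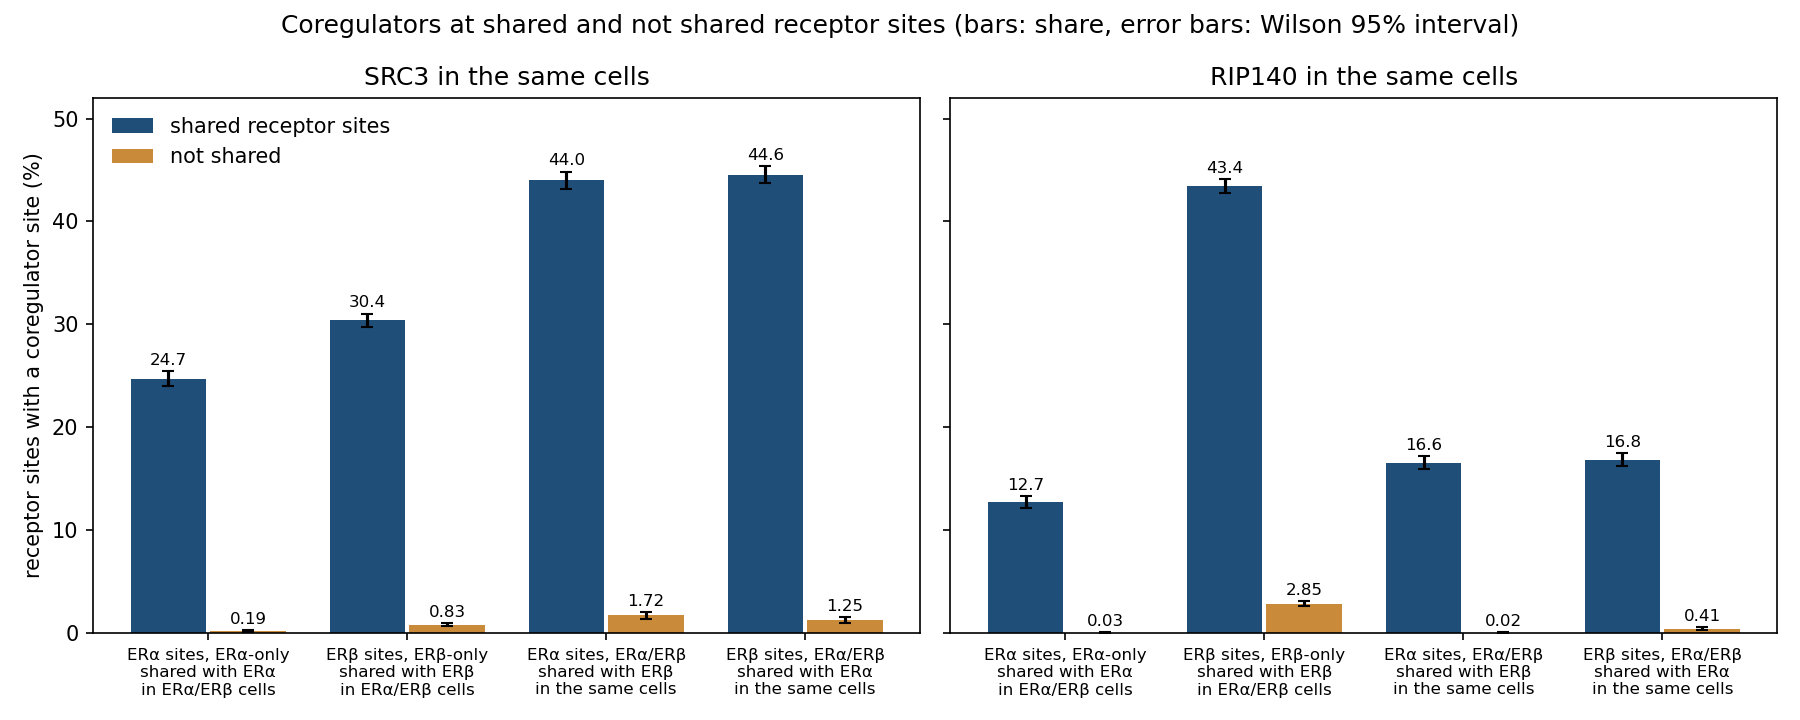
Percent of receptor sites with SRC3 or RIP140 of the same cells, for sites shared with the compared list and sites private to 1 list, with 95% Wilson intervals. Shared sites carry more of both coregulators in every split shown, for example 24.7% against 0.193% for SRC3 at ERα sites kept or not called in ERα/ERβ cells.

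Some of the bands densest in sites recurred across the lists, and others were among the densest in 1 list. Band 20q13.13, within the 20q amplicon of MCF-7 and home to PREX1 and SNAI1, was among the 5 densest bands in 7 of the 10 lists. Bands 14q32.33, 16q24.1 and 21q22.3 (the last with the estrogen-induced TFF1 and TFF3) were in 6 each, and 16p13.3 in 5. Densest here means densest among bands with at least 20 sites. Few bands reach that floor in the short lists, so the floor partly sets which bands recur. Band 16q24.1, with 16 and 18 RIP140 sites in ERα-only and ERα/ERβ cells, could not be ranked in those lists. ERα of ERα-only cells was densest in 16q24.1 (158 sites, 54.5 per Mb, 4.43 times the genome), ERα and ERβ of ERα/ERβ cells in 14q32.33 (35.6 and 47.8 per Mb, 5.50 and 7.28 times), and ERβ of ERβ-only cells in 9q34.2 (64.7 per Mb, 5.28 times). RIP140 was densest in 20q13.13 in ERα-only and ERα/ERβ cells (10.7 and 10.8 times the genome) and in 14q32.33 in ERβ-only cells (7.38 times). SRC3 was densest in 16q24.1 in ERα-only cells (6.85 times), in 20q13.31 in ERβ-only cells (7.46 times) and, in ERα/ERβ cells, in 6p22.1, which holds large clusters of histone and tRNA genes (89 sites, 23.4 per Mb, 10.6 times the genome). Bands known to be amplified in MCF-7 took up 6.15% of the genome and held 8.37% to 10.8% of the sites of each list, and no correction for copy number was possible.

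The share of sites kept between conditions varied widely between bands. ERα sites of ERα-only cells were kept in ERα/ERβ cells most often in 1p35.2 (79.2%, 66.5–88.0), 22q13.1 (64.8%) and 2p25.3 (62.7%), and least often in 1q31.1 (14.5%, 7.83–25.3), 14q12 (15.3%) and 5p14.3 (16.1%). ERβ sites of ERβ-only cells were also called in ERα/ERβ cells most often in 14q32.33 (69.9%), 11q13.3, the band of CCND1 (68.9%), and 7q11.21 (66.7%), and least often in 12q12 (29.8%), 7q11.22 and 16q24.2 (32.1% each). In ERα/ERβ cells, ERα sites carried ERβ most often in 4p16.3 (92.5%), 7q11.21 (91.2%) and 17q25.3 (89.2%), and least often in 2q31.1 (50.8%), 6q27 (51.7%) and 11q14.1 (52.7%). With each receptor alone, ERα sites were ERβ sites most often in 14q32.33 (81.0%), 1p35.2 (79.2%) and 22q13.2 (77.1%), and least often in 1q31.1 (8.06%), 4q28.1 (13.7%) and 6p12.1 (17.1%). SRC3 sites of ERα/ERβ cells were called least often in ERα-only and ERβ-only cells in 6p22.1 (16.9%, 10.5–26.0, and 25.8%, 17.9–35.8), and most often in 21q22.3 (60.3%) and 19p13.3 (78.4%). RIP140 lay at 1.12% (0.199–6.09) of the SRC3 sites in 6p22.1 and at 53.7% of those in 20q13.13. RIP140 sites of ERβ-only cells were found in ERα/ERβ cells most often in 20q13.13 (47.1%) and least often in 10q26.3 (15.3%). These bands are the extremes of the bands with at least 50 sites. There were 308 such bands for ERα sites of ERα-only cells, 267 for ERβ sites of ERβ-only cells and 99 for ERα sites of ERα/ERβ cells. RIP140 sites of ERβ-only cells had 21, and SRC3 sites of ERα/ERβ cells only 7, so the SRC3 bands named do not stand out of many. Shares picked as extremes are more extreme than those a new measurement would be likely to give.

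The widest sites of most classes lay in the amplified bands of chromosomes 17 and 20. Of 78 sites named as the 3 widest of a list or class, each counted once, 66 (84.6%) were in bands known to be amplified. The widest of all was a RIP140 site of ERβ-only cells on chromosome 17 (56814764 to 56854221, 39458 bp, 17q23.2, the band of TBX2 and BCAS3). The widest ERα and SRC3 sites of ERα/ERβ cells (56814857 to 56834930, 20074 bp, and 56841344 to 56847960, 6617 bp) and the widest ERβ site of ERβ-only cells (56817735 to 56834936, 17202 bp) lay in the same region. On chromosome 20, the widest ERα site kept in ERα/ERβ cells was at 55265903 to 55273327 (7425 bp, 20q13.31) and the widest not called there at 51701799 to 51709012 (7214 bp, 20q13.2, the band of ZNF217). The widest ERβ site of ERα/ERβ cells, at 45722746 to 45752956 (30211 bp, 20q13.12, the band of NCOA3 itself), was not called in ERβ-only cells. Among SRC3 sites of ERα/ERβ cells, the widest without a counterpart in ERα-only cells was at 45418506 to 45423973 (5468 bp, 20q13.12). Width stands in for a score here, and copy number can raise it.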

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

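The tests in this part were all chosen after the lengths and widths of the lists had been seen. Going from ERα/ERβ to ERβ-only cells, the coregulators moved in opposite directions: the RIP140 list was 3.55 times as long, and the SRC3 list 0.886 times as long. With 1 list each, the difference between these ratios was not tested.

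The longer RIP140 list also had wider sites: RIP140 sites found in both kinds of cells were 2.15 times as wide in the ERβ-only list (median 739 against 343.5 bp), while SRC3 sites found in both were 0.984 times as wide, which longer fragments, other calling settings, more reads or stronger signal in that RIP140 library could each give. This value largely restates the wider sites already seen in the whole list and does not single out a cause. Of the 6632 RIP140 sites added in ERβ-only cells, 92.1% (91.4–92.7) lay at receptor sites already called in ERα/ERβ cells, which a more sensitive library of the same sites could give. The tables argue against new ERβ sites as the main source, since 5.87% (5.33–6.46) of the added sites lay at ERβ sites that were not receptor sites of ERα/ERβ cells. More RIP140 at existing receptor sites once ERα is depleted stays open and untested, because depth, height and calling settings are not known.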

How the results depend on the processing

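The values below are the shares of the report recomputed with 1 choice changed at a time, all with alternatives fixed beforehand. Unless noted, shares are in percent, in the order of the report, and a value is given where it left the 95% interval of the reported value. None of the 44 shares and differences left it when an overlap of at least 50% of the shorter site was required or when amplified bands were removed, and none of the 10 shares in amplified bands did when touching sites were merged. None of the 16 differences in coregulator shares changed sign under any setting run for them. The cause of the changes was not tested, except where the setting itself fixes it: sites within 500 bp can only add overlaps, and draws from a union that holds the compared lists lower every ratio to chance.

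With sites within 500 bp counted as shared, 16 of 44 values rose past their interval, by at most 1.06 times. ERα sites of ERα-only cells shared 40.0 with ERα/ERβ cells, and 76.1 in the other direction. ERβ sites of ERβ-only cells shared 51.0 with ERα/ERβ cells, and 93.4 in the other direction. ERα with ERβ gave 72.2 and 69.3 in ERα/ERβ cells, and 49.7 and 49.1 with each receptor alone. SRC3 sites of ERα/ERβ cells shared 47.4 with ERα-only cells, 66.5 with ERβ-only cells and 36.4 with RIP140. Differences in points were 43.8 for SRC3 and 17.5 for RIP140 at ERα sites by ERβ, 41.4 for RIP140 at ERβ sites of ERβ-only cells, 13.3 for RIP140 at ERα sites of ERα/ERβ cells by ERα-only cells, and 32.0 for SRC3 at ERβ sites of ERα/ERβ cells by ERβ-only cells.

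In the widest 50% of each list, 51 of 54 values left their interval; of all 54, 14 were higher and 40 lower. ERα sites of ERα-only cells shared 32.1 with ERα/ERβ cells (62.3 in the other direction), and ERβ sites of ERβ-only cells 43.2 with ERα/ERβ cells (81.2). ERα with ERβ gave 54.6 and 52.7 in ERα/ERβ cells, and 38.3 and 38.1 with each receptor alone. SRC3 sites of ERα-only and ERβ-only cells shared 73.3 and 68.1 with ERα/ERβ cells, and those of ERα/ERβ cells 43.6 and 60.5 with them. For RIP140 the same 4 shares were 63.2, 21.5, 53.5 and 77.9. Receptor sites lay at 87.5, 89.4 and 85.8 of SRC3 sites and at 84.8, 93.9 and 88.5 of RIP140 sites in ERα-only, ERα/ERβ and ERβ-only cells. RIP140 sites had SRC3 at 83.5, 92.5 and 45.1, and SRC3 sites had RIP140 at 43.7 in ERα-only and 67.9 in ERβ-only cells. Differences in points for SRC3 and RIP140 were 25.9 and 13.9 at ERα sites of ERα-only cells, 22.7 and 34.5 at ERβ sites of ERβ-only cells, 19.7 and 11.5 at ERα sites of ERα/ERβ cells by ERα-only cells, 17.7 and 8.02 at ERβ sites of ERα/ERβ cells by ERβ-only cells, and 40.7 and 18.2 at the latter by ERα. For SRC3 at ERα sites by ERβ the difference was 30.2. With each receptor alone it was 17.2 for SRC3 at ERα sites by ERβ, and 20.1 and 23.4 for SRC3 and RIP140 at ERβ sites by ERα. Amplified bands held 10.3 and 9.76 of ERα sites, 10.8 and 10.0 of ERβ sites, 10.4, 10.8 and 10.8 of SRC3 sites and 12.8, 13.4 and 10.1 of RIP140 sites.

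With the longer list reduced to the length of the shorter, 32 of 44 values moved. The gaps between the directions of a pair narrowed, as equal lengths require, except for the receptors alone, whose lists were already of similar length. ERα sites of ERα-only and ERα/ERβ cells shared 46.4 and 48.2, and ERβ sites of ERβ-only and ERα/ERβ cells 62.6 and 63.7. ERα sites of ERα/ERβ cells had ERβ at 69.8. SRC3 sites of ERα-only and ERβ-only cells shared 58.8 and 68.5 with ERα/ERβ cells, and 59.0 and 68.5 in the other direction. For RIP140 these shares were 61.5 and 39.8, and 61.6 and 42.1. Receptor sites lay at 36.0, 45.4 and 32.1 of SRC3 sites and at 29.8, 28.0 and 42.2 of RIP140 sites. RIP140 sites had SRC3 at 70.1, 68.1 and 63.5, and SRC3 sites had RIP140 at 69.7, 67.6 and 65.5. Differences in points were 32.6 and 17.9 for SRC3 and RIP140 at ERα sites of ERα-only cells, 34.1 and 46.3 at ERβ sites of ERβ-only cells, 14.8 for RIP140 at ERα sites of ERα/ERβ cells by ERα-only cells, and 16.1 and 10.6 for SRC3 and RIP140 at ERβ sites of ERα/ERβ cells by ERβ-only cells.

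Against random draws from the union of all 10 lists, all 28 ratios to chance were lower than against circular shifts, and 2 of 28 fell below 1: ERα with ERβ when each was alone, 0.760 and 0.755 times the draws. The union contains the compared lists, and these 2 are among its longest, so a ratio below 1 is nearly fixed by construction for them and is no evidence against their overlap. The other ratios were 1.19 and 1.19 for ERα between cells, 1.49 and 1.48 for ERβ between cells, and 2.13 and 2.12 for ERα with ERβ in ERα/ERβ cells. SRC3 gave 7.10, 6.71, 7.06 and 6.57 between cells and 1.49, 2.26 and 1.58 at receptor sites. RIP140 gave 16.5, 6.32, 16.6 and 6.36 between cells and 1.44, 2.26 and 1.56 at receptor sites. RIP140 with SRC3 gave 13.6, 8.72 and 5.91, and the other direction 13.5, 8.55 and 5.97.

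Gene windows of 20 kb and 100 kb and gene lists in the widest 50% of each list were not run, because they need a gene annotation on hg18, which was not used here.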

Other observations

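All tests in this part were chosen after the pattern they concern had been seen.

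ERα sites that were not called once ERβ was present were nearly free of coregulators. Narrow sites alone do not account for this, since SRC3 lay at 0.308% (0.195–0.486) of the 5845 of them at least 775 bp wide and at 38.7% (37.5–39.9) of kept sites of that width, although width is not signal and weak binding stays open. False calls spread evenly over the genome are argued against as the source of all lost sites. The bands densest in kept sites held 42.8% of the lost sites, 1.72 (1.70–1.75) times their share of the genome. This value lies between an even spread and the 2.26 times of kept sites, so a part of the lost sites could still be such false calls. Calls that favour open chromatin were not tested. Replacement by called ERβ at most of these positions is argued against, since ERβ of ERα/ERβ cells lay at 8.19% (7.84–8.55) of them. The longer ERβ list of ERβ-only cells lay at 22.6% (22.03–23.10). ERβ too weak to be called cannot be told from no ERβ. A loss of weaker ERα binding when ERβ is expressed, or a shallower ERα library of ERα/ERβ cells, could each give such a list. ERα sites found in both kinds of cells were 0.758 times as wide in the ERα/ERβ list (median 561 against 740 bp). SRC3 sites found in both were 1.02 times as wide in the ERα/ERβ list. The 2 ERα lists thus differ in width even at common sites, which does not tell these explanations apart.

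The few SRC3 sites outside receptor sites of any cells gathered in band 6p22.1. These were 15 of 110 (13.6%) in ERα-only, 21 of 66 (31.8%) in ERβ-only and 84 of 212 (39.6%) in ERα/ERβ cells. Their number was largest in ERα/ERβ cells, where the 84 lay between 26413510 and 29058132 on chromosome 6. Pull-down of the region whatever the antibody is argued against at the share seen for SRC3. Of 78 RIP140 sites outside receptor sites in ERα/ERβ cells, 0 lay there (upper limit 4.69%). That RIP140 list is shorter than the SRC3 list (2511 against 6831 sites), so weaker pull-down could be missed. In all, RIP140 had 0, 1 and 3 sites in the band in ERα-only, ERα/ERβ and ERβ-only cells. A candidate explanation is binding at tRNA genes. Without chromosomes 1 and 6, 96 of the 212 SRC3 sites outside receptor sites in ERα/ERβ cells remained. Over these 21 chromosomes their number went with tRNA genes (r = 0.738) more closely than with protein-coding genes (r = 0.348). Every site in 6p22.1 is left out of this relation, so it concerns the SRC3 sites elsewhere and cannot decide the gathering in that band. In the other lists r with tRNA genes was 0.838 and 0.387 for SRC3 in ERα-only and ERβ-only cells (72 and 33 sites) and 0.594, 0.434 and 0.276 for RIP140 in ERα-only, ERα/ERβ and ERβ-only cells, against 0.362, 0.160, 0.448, 0.538 and 0.695 with protein-coding genes, so tRNA genes gave the higher r in all 3 SRC3 lists and in 1 of 3 RIP140 lists. With all 23 chromosomes r with tRNA genes was 0.861, 0.948 and 0.906 for SRC3 and 0.192, 0.286 and 0.236 for RIP140, but chromosomes are few and coarse, no site was placed at a gene, and no biological cause was tested.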
